A study of Mus musculus with 2 samples.

How the data were processed

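Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on hearts of C57BL/6 mouse embryos at stage E12.5. Per the labels' protocols, 1 library came from chromatin pulled down with 2 µg of a rabbit antibody against Sap130, with a Diagenode kit for transcription factors, and 1 library was input DNA taken without antibody. Both were prepared with an NEBNext kit for Illumina sequencing. Sap130 is a subunit of the Sin3 histone deacetylase complex, a corepressor that removes acetyl groups from histones.

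The submitters' processing notes name Bowtie 1.1.2, an aligner, MACS2 2.1.0.20140616, a peak caller, and the mouse genome build GRCm38 (mm10). How these were run, how duplicate reads and reads with several matches were treated, and which threshold was set are not given in the sources used here. The deposited list holds 14886 entries, each 1 base long, taken as peak summits, with a score that the authors deposited as the −log10 of a p-value or q-value. Which of the 2 it is could not be settled from the values. A score of this kind grows with sequencing depth as well as with enrichment, so it was used only to rank and filter summits within this list. It gives no fold over input. Read counts and peak widths were not used here, so the depth of both libraries is unknown, and the input entered only through the authors' peak calling.

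Genes were taken from a RefSeq table of the same build, GRCm38.p6, with the first and last base of each gene. The table gives no strand, transcript starts, exons or sequence. Promoters as planned, within 1000 bp of a protein-coding transcript start, were therefore replaced by gene ends: a summit was at a gene end when it lay within 1000 bp of either boundary of a protein-coding gene. This takes in the last base of a gene as well as its start, and misses starts inside a gene. Of 49997 annotated genes, 394 were left out, of which 121 were protein-coding: those of the mitochondrial genome, those on no named chromosome, and those starting in the first 3 Mb of a chromosome other than Y, which were taken as scaffolds and patches. The 21779 protein-coding genes left were used throughout.

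Each summit was put in 1 of 4 classes: at a gene end, elsewhere inside a protein-coding gene, at or in a gene of another type, and intergenic. Shares carry Wilson 95% intervals. They were set against 1000 random placements of the summits on their own chromosomes, between the first and last annotated gene or summit, since assembly gaps were not known, with a one-sided permutation p. Scores at gene ends and elsewhere were compared by a two-sided permutation test of the difference of medians with 100000 resamples. For 32 gene lists, the share of members with a summit at an end was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 32 lists at 0.05 and exact (Clopper-Pearson) 95% intervals. The median score of each list was also ranked among the medians of 10000 random lists of the same size drawn from genes with a summit. The lists hold 2405 genes, of which 34 stand in 2 or more lists, and no symbol went unmatched.

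With 1 ChIP library there is no replicate error. All intervals cover counting error only, and every p-value describes this 1 library, with neighbouring genes and summits that are not independent replicates.

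The lists, tests, window and settings were fixed before the data were examined, as was the rule for named genes. The tests under other observations were not part of that plan. The rule takes Sap130 and Pcdha9, and up to 12 members with a summit and 4 without of the Sin3 complex and of the heart transcription factors. It adds the 15 genes with the highest scores, up to 4 members with and 2 without a summit of each other list, and the 5 highest-scoring summits away from gene ends. Not every gene the rule takes is reported here. Settings fixed in advance were windows of 500 and 2500 bp, the 7447 and the 3728 summits of highest score, merging of summits within 500 bp, and genes of any type. The count of 7447 is over all summits, at or above their median score of 33.2908. Tests with this setting took nuclear summits at or above their own median of 33.305. That set is slightly smaller but is named by the 7447 below. Chosen after seeing the data were a shift of all summits of a chromosome together and random lists matched on gene density and length. So were a background of genes with a curated transcript outside the olfactory and vomeronasal families, leaving out summits in reach of 2 or more genes, a reach of 10000 bp around the whole gene, and a count of protocadherin genes by their own left end, against the left ends of other genes. The share of CpG-rich summits and the search for 30 motifs need the genome sequence and were not analysed here.

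Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The list test was tested on 20 simulated data sets over the 21779 genes. It found 99.5% of lists set to a share of 85% and 100% of those set to 15%, and called 2.08% of unchanged lists. Smaller differences were not simulated, so the rates do not tell how often lists nearer to the share of other genes would be found. Each simulated gene was drawn independently, so these rates do not cover lists whose members share summits, such as clustered genes. For the random placements, 50.1% of simulated summits were put at gene ends and 50.2% were recovered after subtracting the random share. Those summits were put within 500 bp of an end and the others at random, so this checks the calculation only. It does not test whether random placement is a fair comparison.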

Results

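Binding of Sap130, a subunit of the Sin3 histone deacetylase complex, was mapped in mouse hearts at stage E12.5 by 1 ChIP library, with peaks called against 1 input library. The stated purpose was to find the targets of Sap130 in the embryonic heart. The list held 14886 peak summits, 14881 of them on 20 nuclear chromosomes of build GRCm38. Chromosome 11 held 1276 summits, X held 420 and Y held 0. Neighbouring summits were a median of 41919 bp apart. The authors' score, a −log10 p or q, ran from 2.1 to 428 with a median of 33.3 and quartiles of 13.9 and 65.2. There was no replicate, the depth was unknown, and intervals cover counting error only.

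Sap130 summits were concentrated at the ends of protein-coding genes. Of the 14881 summits, 10937 (73.5%, 95% interval 72.8 to 74.2) lay within 1000 bp of a gene boundary, against 3.26% ± 0.147 (SD over 1000 random placements), a 22.6-fold excess. A further 3261 summits (21.9%, interval 21.3 to 22.6) lay elsewhere inside protein-coding genes, below the random 39.4%. Genes of other types held 424 summits (2.85%, random 9.40%), and 259 (1.74%, random 48.0%) were intergenic. The one-sided permutation p was 0.001 for the excess at gene ends and for the deficit in each other class, the smallest that 1000 placements can give. The median distance from a summit to the nearest gene boundary was 327 bp, against 46270 bp in 1 random placement. Without strand, a gene's first and last bases could not be told apart.

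Summits at gene ends lay mostly just inside the gene. Of 9144 summits in reach of 1 gene only, 7865 were inside that gene (86.0%, Wilson interval 85.3 to 86.7), at a median of 243 bp from its boundary (quartiles 182 and 407 bp). Those outside lay at a median of 307 bp. The 50 bp bin from 200 to 250 bp inside held the most summits, 1561, while the bin of the first 50 bp inside held 95 and the 50 bp outside held 52. Among 18416 genes longer than 3000 bp, 9679 had a summit at 1 end only, 4816 at the left and 4863 at the right as the chromosome is numbered, and 249 at both. Another 1793 summits were in reach of 2 or more genes and cannot be given to 1 of them.

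**Figure D1:**
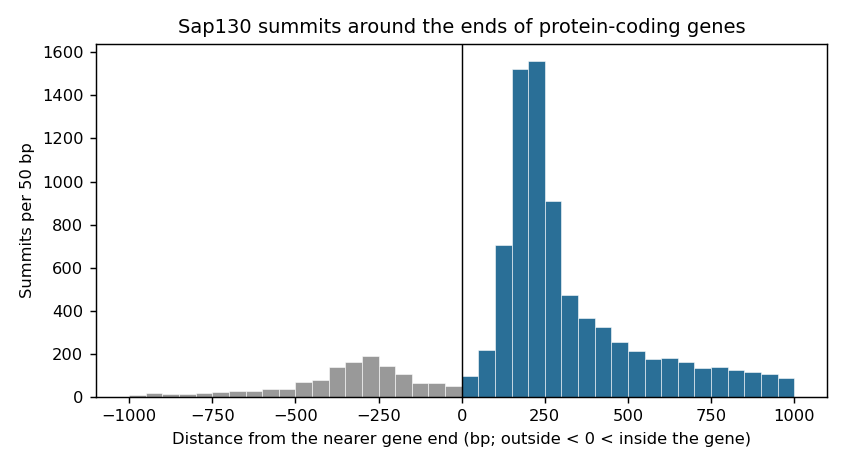
Number of Sap130 summits (vertical axis) by position relative to the nearest boundary of a protein-coding gene in 50 bp bins (horizontal axis, bp), for the 9144 summits in reach of 1 gene only. The highest bin, 200 to 250 bp inside the gene, holds 1561 summits and the 50 bp just outside hold 52.

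Summits at gene ends had higher scores than others. Their median score was 40.4, against 17.6 for the other summits, a difference of 22.8 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Among the 7447 highest-scoring summits the medians were 66.3 and 60.5, a difference of 5.78 (permutation p = 2e-05). Summits elsewhere inside protein-coding genes had a median score of 19.5, those in other genes 13.2 and intergenic ones 12.8. In 10 bins of near-equal size ordered by score, the share at gene ends was 49.3% (Wilson interval 46.8 to 51.9) for the lowest scores and 86.8% (85.0 to 88.4) for the highest.

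**Figure D2:**
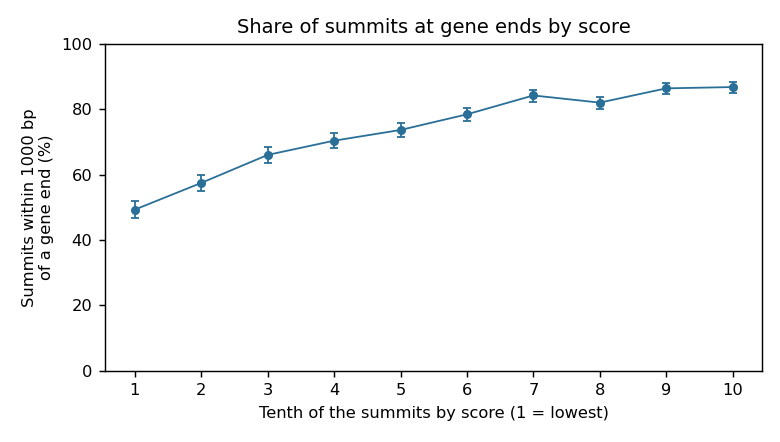
Share of summits within 1000 bp of a protein-coding gene boundary (vertical axis, percent) in 10 bins of near-equal size ordered by the authors' score (horizontal axis). Points are shares with Wilson 95% intervals, from 49.3% at the lowest scores to 86.8% at the highest.

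A summit at an end was found for 10532 of 21779 protein-coding genes (48.4%, Wilson interval 47.7 to 49.0), with a median score of 49.3. The highest score, 428, was at Ncl, which encodes the nucleolar protein nucleolin (chromosome 1, 86344719 to 86359455, summit at 86358774, 681 bp inside the gene). A single summit of score 372 was in reach of both Mettl1, a tRNA methyltransferase, and Eef1akmt3, a methyltransferase of a translation elongation factor. Trmt61a, of the tRNA m1A methyltransferase, had 336, and Trmt2a, another tRNA methyltransferase, shared a summit of 282 with Ranbp1, a regulator of the Ran cycle of nuclear transport. Nol9, a kinase of ribosomal RNA processing, had 315, Mdn1, a remodeller of ribosome precursors, 277, and Gar1, of H/ACA ribonucleoproteins, 275. The cell cycle genes Ccne2 (cyclin E2), Ccnb2 (cyclin B2) and Fbxo5, an inhibitor of the anaphase-promoting complex, had 315, 306 and 296. Crebrf had 296, Sec31a, a COPII coat protein of vesicles leaving the endoplasmic reticulum, 279, and Scfd2 276.

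Genes of the Sin3 complex itself carried Sap130 summits more often than other genes. A summit was at an end of 28 of 31 genes (90.3%, exact interval 74.2 to 98.0), against 48.3% of the other genes (Fisher's exact test, adjusted p = 3.5e-06), and their median score of 80.1 stood at percentile 99.8 of random lists. Sap130 had a summit of score 138 at its own left end (chromosome 18, 31634368 to 31723068, summit at 31634576, 208 bp inside). Arid4a, which encodes an ARID domain subunit, had 148 and its relative Arid4b 94.6. The PHD finger genes Phf12 and Ing1 had 138 and 126, and the subunit genes Suds3, Sap30l, Sap30 and Rbbp4 had 112, 111, 102 and 91.9. The Sin3-binding repressor gene Mxd1 and the histone demethylase gene Kdm5a both had 104, and Foxk1, of a forkhead factor, had 91.9. Sin3a, the scaffold of the complex, had none by this measure, its nearest summit lying 1312 bp inside the gene. Sinhcaf, with a summit 1795 bp inside, and Sap25, with the nearest at 12133 bp, had none either. Kdm5a, Arid4b and Rbbp4 shared their summits with a neighbouring gene.

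Other corepressors and chromatin enzymes were also above the rest. Summits were at 22 of 27 genes of the NuRD, CoREST and NCoR complexes (81.5%, exact interval 61.9 to 93.7, Fisher's exact adjusted p = 0.00107), among them Gatad2a (151), Mbd3 (132) and Chd4 (98.6), but not Rcor2 or Zmynd8. The nearest summit lay 1239 bp inside Rcor2 and 93833 bp outside Zmynd8. Of 59 histone and DNA modifying enzymes and remodellers, 54 had one (91.5%, interval 81.3 to 97.2, adjusted exact p = 1.09e-11). Scores there were highest at Pbrm1 (197) and Smarcc1 (168) of SWI/SNF remodellers, the acetyltransferase gene Kat2a (135) and the methyltransferase gene Ehmt2 (134). The Pbrm1 summit was shared with a neighbouring gene. The histone demethylase genes Kdm6a and Kdm6b had none within reach, with summits 1216 and 1056 bp inside.

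Lists of genes for basic cell functions had summits in 84.6% to 97.9% of their members. The share was 97.9% of 48 autophagy and lysosome genes (exact interval 88.9 to 99.9), 93.3% of 75 nuclear genes of the respiratory chain and ATP synthase (85.1 to 97.8), 92.3% of 52 cell cycle genes (81.5 to 97.9) and 92.2% of 51 spliceosome genes (81.1 to 97.8). It was 89.6% of 77 mitochondrial ribosomal protein genes, 88.9% of 81 cytoplasmic ones, 86.2% of 58 DNA replication and repair genes and 84.6% of 39 proteasome genes. Fisher's exact adjusted p ran from 1.05e-15 for the respiratory chain to 6.93e-06 for the proteasome. Examples were Lamp1, a lysosomal membrane protein (207), Vps33a, of vesicle fusion (206), Ndufv1, of complex I (159), Wee1, a mitotic inhibitor kinase (263), and Bub1, a spindle checkpoint kinase (249). Others were the splicing factor gene Srsf7 (173), Mrpl12 of the mitochondrial ribosome (162), Rpsa and Rps19 of the cytoplasmic ribosome (187 and 174), Mcm3 of the replicative helicase (148) and Psmc2 of the proteasome (150). The summits of Srsf7, Mrpl12 and Psmc2 were shared with a neighbouring gene. Median scores of the cell cycle, cytoplasmic ribosome, spliceosome and autophagy lists, 83.7, 73.2, 78.2 and 69.8, lay at percentiles 100, 99.99, 99.97 and 99.48 of random lists. Those of the respiratory chain (51.6), proteasome (57.4), mitochondrial ribosome (56.0) and DNA replication lists (60.0) lay within the random range, at percentiles 64.3, 81.7, 86.0 and 92.5. Members without a summit at an end included Ccna2, Mcm7, Rpl22 and Pik3c3, with the nearest summit 1178, 1041, 1582 and 7437 bp inside the gene. Without summits in reach of 2 or more genes, the difference from other genes fell from 45.1 to 17.0 percentage points for the respiratory chain, from 43.9 to 24.4 for the spliceosome and from 37.9 to 18.8 for DNA replication and repair, all still past the threshold. For the mitochondrial ribosome it fell from 41.4 to 10.4, no longer past it (adjusted exact p = 0.0953).

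**Figure D3:**
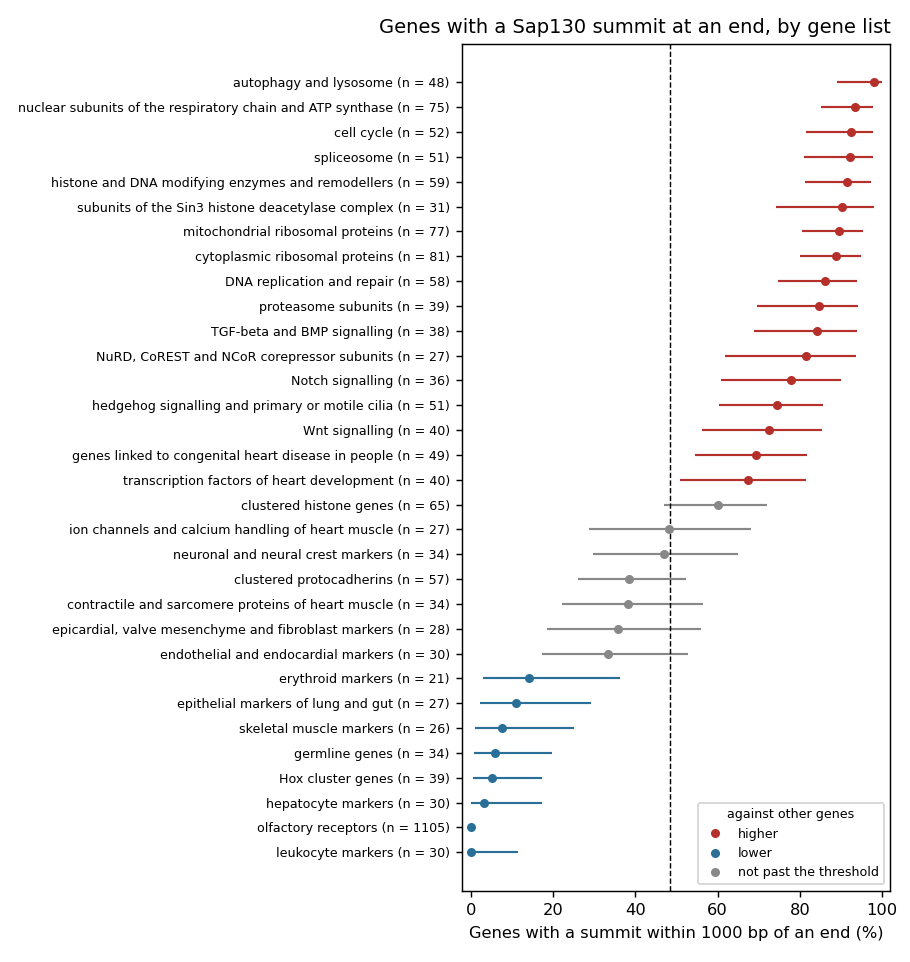
Share of the genes of each list with a Sap130 summit within 1000 bp of an end (horizontal axis, percent), with exact 95% intervals and the number of genes beside each list; the dashed line marks all protein-coding genes, 48.4%. Red lists were higher and blue lists lower than other genes by Fisher's exact test after adjustment, from 97.9% for autophagy and lysosome genes to 0% for leukocyte markers, and grey lists were not past the threshold.

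Genes of developmental signalling had summits more often than other genes, with scores near those of other targets. They were found at 32 of 38 TGF-beta and BMP genes (84.2%, exact interval 68.7 to 94.0, Fisher's exact adjusted p = 1.14e-05), 28 of 36 Notch genes (77.8%, 60.8 to 89.9, p = 0.000591), 38 of 51 hedgehog and cilia genes (74.5%, 60.4 to 85.7, p = 0.000336) and 29 of 40 Wnt genes (72.5%, 56.1 to 85.4, p = 0.0033). Genes linked to congenital heart disease in people had them in 34 of 49 cases (69.4%, 54.6 to 81.7, adjusted exact p = 0.00509). Named members were Smurf1, a ubiquitin ligase of BMP signalling (104), Bmpr2, a BMP receptor (76.6), Numb, a Notch inhibitor (92.9), and Dvl1 and Gsk3b of the Wnt pathway (158 and 107). Ift74, of intraflagellar transport, had 155, the cohesin gene Smc3 129 and the phosphatase gene Ptpn11 124. The summits of Dvl1 and Ift74 were shared with a neighbouring gene. Members without a summit at an end included Bmp4, Dll3 and Shh, with the nearest summit 1933, 1244 and 1223 bp inside the gene, and Ihh and Wnt1, with the nearest 9717 and 26974 bp outside. The Wnt and heart disease lists were not past the threshold with a window of 500 bp (adjusted exact p = 0.0709 and 0.056), nor the hedgehog list without summits in reach of 2 or more genes (0.0976). The Notch difference fell from 29.5 to 18.9 points at 500 bp, and the hedgehog one from 26.2 to 16.0 against lists matched on gene density and length, both still past the threshold. All 5 of these lists lost their call among the 3728 summits of highest score (adjusted exact p from 0.056 to 0.696), and the Notch list already among the 7447 highest (0.111).

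Transcription factors of heart development had summits more often than other genes but with low scores. A summit was at 27 of 40 genes (67.5%, exact interval 50.9 to 81.4, Fisher's exact adjusted p = 0.022), with a median score of 21.0, at percentile 0.05 of random lists. With the 7447 highest-scoring summits alone, their share was instead below that of other genes, a difference of -19.2 percentage points (adjusted exact p = 0.011). The call was also lost with a window of 500 bp (0.122) and against curated genes (0.0954), while with 10000 bp around the gene the difference was 30.0 points in place of 19.2 (adjusted exact p = 9.96e-05). Scores were 116 at Mef2d and 83.3 at Tead1, which encode factors active in muscle, 36.4 at Nfatc1, a factor of valve formation, 31.3 at Foxc2, 31.1 at Zfpm2, a GATA cofactor, and 28.4 at Hand2, a factor of right ventricle formation. Hey1, a Notch target, had 28.7 from a shared summit, Meis2 and Meis1 26.5 and 23.4, and Irx5, linked to the repolarisation gradient, 23.0. Foxh1, a SMAD partner, had 176 and Srf, serum response factor, 46.9, both from summits shared with a neighbouring gene. Gata4, Gata5, Tbx1 and Tbx3 had no summit at an end. The summit nearest to an end was 5204 bp outside Gata4, 1552 bp inside Gata5, 30463 bp from Tbx1 and 150648 bp from Tbx3. Gata4 also held 1 summit inside the gene, farther from its ends, with a score of 29.5.

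Genes of the contracting and lining cells of the heart did not differ from other genes in this test. Summits were at 13 of 34 sarcomere genes (38.2%, exact interval 22.2 to 56.4, Fisher's exact adjusted p = 0.323) and 13 of 27 ion channel and calcium handling genes (48.1%, 28.7 to 68.1, p = 1). They were at 10 of 30 endothelial and endocardial markers (33.3%, 17.3 to 52.8, exact p = 0.123) and 10 of 28 epicardial, valve and fibroblast markers (35.7%, 18.6 to 55.9, p = 0.211). The median score of the sarcomere genes was 9.51, below all 10000 random lists (percentile 0). Median scores of the endothelial, epicardial and ion channel lists were also low, 17.1, 19.1 and 25.3, at percentiles 0.47, 0.97 and 3.74. Pdlim5, of the Z-disc, had 77.1, Actn2, cardiac alpha-actinin, 26.0, and the myosin heavy chain genes Myh6 and Myh7 none. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had 88.6, Gjc1, connexin 45, 119, and Kcnq1 none at an end, though 2 inside the gene. Klf2, a flow-responsive factor of endothelium, had 33.0, Vim, vimentin, 58.3 and Tbx18 20.5, while Pecam1, Cdh5 and Tcf21 had none. With the 7447 highest-scoring summits alone the sarcomere, endothelial and epicardial lists were below other genes, with differences of -28.8, -21.7 and -24.5 percentage points (adjusted exact p = 9.65e-05, 0.011 and 0.00509), and against curated genes the endothelial list was too (-20.2 points, 0.0387).

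Markers of blood and of tissues other than the heart had summits less often than other genes. They were at 0 of 30 leukocyte genes (exact interval 0 to 11.6, Fisher's exact adjusted p = 8.78e-09), including Ptprc, and at 1 of 30 hepatocyte genes (3.33%, 0.0844 to 17.2, p = 2.17e-07), Apoa2 with 8.91 from a shared summit, while Alb and Afp had none. Germline genes had 2 of 34 (5.88%, 0.720 to 19.7, p = 2.52e-07), skeletal muscle genes 2 of 26 (7.69%, 0.946 to 25.1, p = 2.46e-05) and lung and gut epithelial genes 3 of 27 (11.1%, 2.35 to 29.2, adjusted exact p = 0.000107). Foxj1, a factor of motile cilia, had 116, whereas the summits counted for Actn3, Mylpf, Gdf9 and Sftpc lay outside these genes and were shared with a neighbour. Erythroid genes had 3 of 21 (14.3%, 3.05 to 36.3, Fisher's exact p = 0.00241 after adjustment): Tfrc, the transferrin receptor of all dividing cells, with 132, Sptb with 16.2 and Tal1 with 8.68, while Hba-a1 and Hba-a2 had none. Without summits in reach of 2 or more genes the erythroid adjusted exact p was 0.0533, and it was 0.155 with 10000 bp around the gene, a reach that also ended the germline call (0.197). With the 3728 highest-scoring summits alone the erythroid, epithelial and skeletal muscle calls ended (adjusted exact p = 0.179, 0.0887 and 0.0887). The 3 lists stayed below other genes there, by -12.5, -13.6 and -13.4 points, when only 3761 genes in all had a summit at an end. Neuronal and neural crest markers did not differ from other genes, with 16 of 34 (47.1%, 29.8 to 64.9, adjusted exact p = 1), Grin1 and Elavl3 having 51.0 and 38.3, but were lower with the 7447 highest-scoring summits (-22.9 points, adjusted exact p = 0.00395).

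Among genes that lie in clusters, the Hox clusters, which pattern the body axis, had summits at 2 of 39 genes (5.13%, exact interval 0.627 to 17.3, Fisher's exact adjusted p = 1.37e-08), Hoxd1 with 9.61 and Hoxd8 with 5.80. Olfactory receptors had 0 of 1105 (interval 0 to 0.333). Clustered histone genes had 39 of 65 (60.0%, 47.1 to 72.0, adjusted exact p = 0.0775) with a low median score of 13.9, and were below other genes with the 7447 highest-scoring summits (a difference of -22.5 points, adjusted exact p = 4.79e-05). Against random lists matched on gene density and length they were above (32.1 points, adjusted permutation p = 0.000376), as with 10000 bp around the gene (26.2 points, adjusted exact p = 1.24e-05). Histones, olfactory receptors and protocadherins have close copies in which reads can be hard to place.

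Pcdha9, a protocadherin of the alpha cluster that is linked with Sap130 to a hypoplastic left heart in mice, had no summit at either end (chromosome 18, 36997880 to 37187657). The nearest summit to its ends lay 30574 bp outside, and 2 summits lay within its span, at 37143872 and 37144162. These were 194 and 484 bp inside the left end of Pcdhac2, a gene of the same cluster whose span overlaps that of Pcdha9. Of 57 clustered protocadherin genes, which encode neural cell adhesion proteins, 22 had a summit at an end (38.6%, exact interval 26.0 to 52.4, Fisher's exact adjusted p = 0.167). These were 1 of 14 alpha, 0 of 22 beta and 21 of 21 gamma genes. The gamma genes share their right end, near which 1 summit of score 12.8 lay, at 37842596. Counted by their own left end, a choice made after seeing the data, 3 of 57 genes had a summit (5.26%, 1.1 to 14.6), against 25.0% of the left ends of other genes (adjusted exact p = 0.00067): Pcdhgc3 with 42.8, Pcdhgc4 with 14.8 and Pcdhac2 with 13.3. By either end, the list was also below other genes at 500 bp (-37.1 points, adjusted exact p = 1.51e-09), without shared summits (-31.3, 2.5e-07) and with the 7447 and 3728 highest-scoring summits (-30.0 and -17.3, 3.7e-08 and 0.000118). Each of these settings drops the 1 summit at 37842596, which lay 726 bp outside Pcdhga1 with 24 genes in reach. They are therefore not independent of each other or of the count by left ends. With that summit kept, the list was narrowly below other genes against matched lists (-12.7, permutation, 0.0372) and curated genes (-14.9, 0.0403). It was not past the threshold at 2500 bp (-14.1, adjusted exact p = 0.0559), and with 10000 bp around the gene the sign turned (1.35, 0.922).

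**Figure D4:**
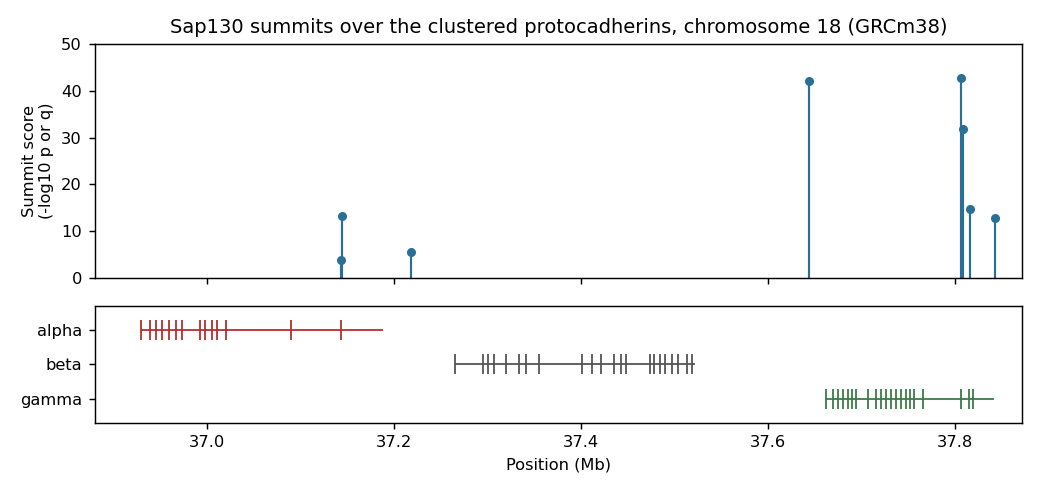
Map of the alpha, beta and gamma protocadherin clusters on chromosome 18 (horizontal axis, position in GRCm38), with the left end of each gene as a tick in the lower panel and Sap130 summits in the upper panel at the height of the authors' score (vertical axis, −log10 p or q). Only 3 of the 57 genes have a summit at their own left end, the highest being Pcdhgc3 with 42.8.

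Away from gene ends, 3944 summits lay over 1000 bp from every protein-coding gene boundary. The highest score among them, 313, was on chromosome 5 at 142367616, 33881 bp from Foxk1 and at the lncRNA gene Gm31068. The next 4 lay inside genes: 248 in Wdr4, a partner of the Mettl1 tRNA methyltransferase (chromosome 17, 31512173, 7812 bp from its nearer end), 230 in Npm1, nucleophosmin (chromosome 11, 33162481, 1661 bp), 229 in Set, a histone chaperone (chromosome 2, 30067351, 5226 bp), and 217 in Ino80, a chromatin remodeller (chromosome 2, 119477099, 1586 bp). Transcript starts within genes were not known here.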

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

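No test was chosen after the result was seen in this part, since none was run. The mitochondrial genome, which lies outside the comparisons on nuclear genes, held 5 summits, at positions 459, 4159, 12018, 13667 and 15436, with low scores from 3.56 to 7.44. They drew attention because a signal stood in sequence that the comparisons did not use, at 5 summits in a genome whose last annotated base is 15422, against 5.79 summits per Mb of nuclear chromosomes. Read depth over either genome was not known here, so this contrast of densities does not measure enrichment.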

How the results depend on the processing

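Chosen after seeing the data were the shifted placements, the matched lists, the curated background, the removal of shared summits, the reach of 10000 bp around the gene and the protocadherin left ends. Of 25 settings of the main results, 21 gave the same reading. For shares and score differences this means that direction and call were kept. Counts had only to stay within a fixed fold of the main count, as with 7936 genes against 10532, and the gene lists entered by their number past the threshold. Which lists these were changed more: of the 25, 16 kept their call at the strictest score limit, where 21 were called, and 23 at the stricter one, where 30 were called, 15 higher and 15 lower. The other settings kept 22 to 25 of them, the curated background 23 of the 24 it could test, as it leaves out the olfactory receptors. The others are smaller by construction: the stricter and the strictest score limit left 7447 and 3728 summits, and 6893 and 3761 genes with a summit at an end. The share at gene ends ran from 61.5% (500 bp) to 86.0% (strictest score). Of 256 settings of the lists, 208 kept direction and call, 18 lost a call, 17 gained one and 13 changed sign. In points against other genes, heart transcription factors went to -19.2 (stricter score) and -9.79 (strictest score), and histones to -22.5 (stricter score), -12.7 (strictest score) and -4.14 (no shared summits). Ion channels went to 10.3 (2500 bp), 8.02 (no shared summits) and 14.0 (10000 bp), and neuronal markers to 6.20, 1.80 and 7.60 in that order. With 10000 bp sarcomere genes went to 1.71 and protocadherins to 1.35. The cause was not tested. For 201 named genes, 541 of 603 settings left the presence or absence of a summit at an end as it was. The CpG-rich share, both motif searches, the CpG-matched lists, the CpG-rich background and the most upstream start were not run for want of sequence and strand. Summits being 1 base long, the midpoint rule changes nothing. No replicate could be left out, and unknown depth limits how far a gene without a summit can be read as unbound.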

Other observations

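Among the tests below, the ones chosen only after the result was seen included the near-identical copies of small RNA genes, the class of ribosome biogenesis genes, the heart transcription factors taken alone, and the matched, curated and shared-summit checks of the lists. The comparison of lists for summits away from gene ends was not among the tests fixed in advance. Nor was that of tRNA with other small RNA genes.

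Genes of ribosome biogenesis and tRNA modification, a class drawn up by symbol after Ncl, Mettl1, Trmt61a, Nol9, Trmt2a, Mdn1 and Gar1 had been seen among the 15 highest scores, were examined without the 15. Of the other 120 genes of the class, 106 had a Sap130 summit at an end (88.3%, exact interval 81.2 to 93.5), against 48.1% of other genes (Fisher's exact p = 2.19e-20). Their median score was 82.9, against 48.9 for other genes with a summit. That median stood at percentile 100 of 10000 random lists, which is consistent with high scores across the class and not at a few genes. Since the class was chosen after its leading members were seen, this remains a hypothesis, and no expression data were used here to compare it with.

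Transcription factors of heart development had summits away from gene ends, inside or near the gene: 25 of 40 (62.5%) against 15.9% in random lists matched on gene length and density (permutation, adjusted p = 0.00213). The count took in summits beside a gene as well as inside it. For Irx5 the highest-scoring one was at 92355961, before the first base of the gene at 92357796. Sarcomere genes, 12 of 34 (permutation, adjusted p = 0.0507), and ion channel genes, 9 of 27 (permutation, adjusted p = 0.27), did not pass. Over the 101 genes of the 3 lists together, 46 (45.5%) had such a summit, against 17.9% (95% range 10.9 to 25.7) in matched random lists. Meis2 had 8, Meis1 7, the calcium channel gene Cacna1c 5, and Foxp1 and Tbx20 4 each, and genes with 3 included Nkx2-5, Hand2 and Gata6. Other lists past the threshold included ribosomal proteins, with 24.7% against 7.14% (permutation, adjusted p = 0.00213), and chromatin modifiers, with 44.1% against 23.4% (permutation, adjusted p = 0.0048). Developmental lists passed too. These were Notch (41.7% against 17.8%, permutation, adjusted p = 0.00747), congenital heart disease (40.8% against 19.7%, 0.00512), Wnt (40.0% against 19.0%, 0.0119) and TGF-beta and BMP genes (39.5% against 20.8%, 0.0384).

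Gene length, matched in 5 bins, does not account for the heart pattern, as the share stood at percentile 100 of the matched lists. Lengths within a bin were not matched, so a part played by the longest genes stays open. Starts of shorter transcripts within genes do not account for all of the heart pattern, since 7 genes (6.93%) had a summit outside every protein-coding gene, against 1.54% in random lists (percentile 99.92). For the rest of the 46 genes such starts stay open. This check took the 3 lists together at all scores and was not made for the transcription factors alone. Weak calls do not account for the transcription factors: among the 7447 highest-scoring summits, 9 of 40 (22.5%) had one, against 6.06%, an excess of 16.4 points (permutation, adjusted p = 0.00896). Over the 3 lists together the excess was no longer beyond the random range, with 11 genes (10.9%) against 7.45% (2.97 to 12.9, percentile 87.52) and 0 of 34 sarcomere genes, so weak calls stay open for the sarcomere and ion channel genes, neither of which passed alone. No biological explanation was tested, since the design has 1 ChIP library and no groups.

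Transfer RNA genes had a summit within 500 bp in 25.8% of 403 cases. Neighbouring protein-coding genes do not account for it: over 5000 bp from any protein-coding gene end, 60 of 297 tRNA genes had one (20.2%), 20.4 times the share of 27 of 2720 snRNA, snoRNA and miRNA genes (0.993%, Fisher's exact p = 2.93e-42). Being multicopy is not enough for such a share, since snRNA genes, also multicopy, had summits at 0.0389 of the tRNA share (1.00%, Fisher's exact p = 6.59e-49). How alike the copies of each kind are, and how reads with several matches were treated, was not known. Near-identical copies therefore stay open as an explanation. Whether weak calls make the pattern stays open: among the 7447 highest-scoring summits, 1.35% of far tRNA genes had a summit, against 0.294% (Fisher's exact p = 0.0241), which met the bound set beforehand for rejecting weak calls, but those 4 genes shared 3 summits, so the genes were not independent and that bound was unsuited (a minimum of 5 distinct summits was set afterwards). The 51 summits behind the pattern had a median score of 12.6 and lay at 29 of 85 groups of tRNA genes, and no biological explanation was tested.

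Gene density and length, matched in 5 bins each, leave the differences between gene lists in place: 25 of the 25 lists past the threshold stayed so against matched random lists. Gene families in which short reads are hard to place do not account for the higher lists, of which 16 of 17 stayed higher against curated genes outside the receptor families. For the lower lists such families stay open: all 7 of the low lists of markers stayed low against the 19542 curated genes, but 53.5% of these had a summit, above the 48.4% of all genes, so that test could not have ended a low call. Summits of neighbouring genes account for few calls, as 22 of 25 lists kept theirs without summits in reach of 2 or more genes. Also open is transcription in the heart, which could set which gene ends carry a summit, and no expression data were used here.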
